A study of Rattus norvegicus with 6 samples.

How the data were processed

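The series holds 6 RNA-seq libraries of rat tendon stem/progenitor cells, 3 cultured for 7 days in F12 medium and 3 in the same medium with 500 uM N-acetyl-L-cysteine (NAC). Per the labels' protocols, RNA was extracted with an RNeasy kit and libraries were made with a SMARTer mRNA-Seq kit. The authors deposited 1 table of FPKM values (fragments per kilobase of gene length, scaled to sequencing depth) for 33300 genes, of which 32545 carry rat Ensembl identifiers and 755 are unannotated loci without a name. Aligner, counting method, strand setting and the authors' tests are not given in the sources used here, so reads of a gene and of an antisense partner cannot be told apart. The genome builds GRCm38 and mm10, which are mouse builds, are named per the submitters' processing notes, while the identifiers are those of rat, so the build behind the coordinates is not given in the sources used here. The 3 NAC columns carry the group and number of their samples. The 3 other columns, headed N with a number, were taken as the Control samples with those numbers by elimination, since the series has 2 groups.

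Each FPKM value multiplied by the deposited gene length was a whole multiple of 1 step per library within a tolerance of 0.01 (100% of values), which gave the number of reads behind each value. These reads summed to 12487215 to 14941949 per library. The total by which the authors had divided differed from that sum by a factor per library, 1.03 ± 0.0122 in Control and 0.916 ± 0.00812 in NAC (SD, n = 3), whose method is not given in the sources used here. A value of 3 reads per library was used as the floor, under which no fold is given when both groups lie there. Counts of reads and floors cover counting error only.

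Genes with a mean FPKM of at least 1 over the 6 libraries were tested (12733 genes, 11425 of them protein-coding and 493 unannotated loci). Values were taken as log2(FPKM + 1), and fold changes are on that scale, which understates the change of genes of low expression. NAC was compared with Control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, group as the only term), with Benjamini-Hochberg adjustment over all tested genes and an adjusted p under 0.05 as the threshold. Gene lists with at least 5 measured members were tested against all other tested genes with limma's camera at its preset correlation of 0.01, adjusted over the 28 of 29 gene lists that had them, and beside it with an estimated correlation and with fry. The 8 marker lists of other cell types were treated in the same way, and 1 had enough members. None of the 11 lists that camera called was called with an estimated correlation. For some of them the estimate lay below the preset, as for the tendon list (-0.031). Its unadjusted camera p still rose from 0.00308 to 0.0312. A call lost with the estimate is thus not always due to members that vary together. Of 824 list entries 21 were found through an older name in a rat RefSeq gene table, used for names only, and 24 had no entry in the deposited table. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

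The design, the lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. The rule took the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap, placeholder names left out. To these it added Itga5, Itgb1, Pik3ca, Akt1, Scx, Mkx, Tnmd, Col1a1, Col3a1, Dcn and Tnc whatever their result. From each list it took up to 4 called members with the lowest adjusted p, or up to 2 of the most abundant where none was called. It gave 122 genes, 108 of them called. Genes named beyond it are said to have been chosen after their values were seen. Replicates were compared before they were averaged: every pair differed by more than sampling noise (chi-square per degree of freedom of the recovered reads 3.46 to 8.71, highest for the 2 pairs with Control 2), so each library counted as 1 replicate. Correlations of log2 values were 0.982 to 0.987 within groups and 0.978 to 0.981 between them. Replicate numbers were not treated as pairs.

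That first set held a pseudocount of 0.1, no filter, a mean FPKM of at least 5, median-of-ratios rescaling, quantile normalization, eBayes without trend or with robust estimation, the replicate number as a block, a minimum absolute log2 fold change of 1, an adjusted p under 0.01, the other list tests and leaving out each library in turn. Library totals in place of the authors' scaling, limma voom on the recovered reads, a mean of at least 10 recovered reads and protein-coding genes only were added after the data were seen. The test was checked on simulated data drawn from the real means, depths and spreads for the comparison of NAC with Control, with known fold changes given to some of 12722 genes. It called 5 of 49 genes changed 1.25-fold, 20 of 48 changed 1.5-fold, 37 of 48 changed 2-fold and 42 of 46 changed 4-fold, with 0 in the wrong direction. Of 114 calls 10 were of unchanged genes (8.77% in 1 run, above the nominal 5%), and 0 genes were called when none was changed. The list test called 5 of 5 lists raised 1.25-fold and 0 of 20 unchanged ones. The simulated genes were drawn independently of each other, so this check does not cover lists whose members vary together. In the real data the estimated correlation was 0.20 for the collagen chains and 0.20 for the cell cycle list. In the simulated data changes of 1.5-fold or less were thus missed more often than called. Far fewer genes were called there (114) than in the real data (1120), which makes the adjusted threshold stricter. The simulated rates therefore need not hold for the real comparison.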

Results

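Gene expression was measured by RNA sequencing in rat tendon stem/progenitor cells, the resident precursor cells of tendon, after 7 days of culture. The cells grew in F12 medium alone (Control, 3 libraries) or in the same medium with 500 uM N-acetyl-L-cysteine (NAC, 3 libraries), a thiol antioxidant that cells use as a source of cysteine. The libraries held 12487215 to 14941949 reads, recovered from the deposited FPKM values, with a mean of 13.3 ± 0.796 M reads in Control and 14.5 ± 0.745 M reads in NAC (SD, n = 3 each). At the median gene length 1 read was worth 0.0584 to 0.068 FPKM, and 3 reads were taken as the floor, which covers counting error only. Between 12569 and 12757 genes per library reached an FPKM of 1. The 10 most abundant genes took 12.6 ± 0.201% of the reads in Control and 15.7 ± 0.264% in NAC (SD, n = 3), and mitochondrially encoded genes 2.09 ± 0.0525% and 2.25 ± 0.0423%. The first principal component held 34.5% of the variance and placed the Control libraries at -16.8 to -11.005 and the NAC libraries at 12.6 to 15.8. The second held 20.5% and set Control 2 apart at -21.8, where the other libraries lay between -4.23 and 10.3. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

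The comparison of NAC with Control asks how NAC changed the transcriptome of these cells, and the series title points to tenogenic differentiation and to integrin α5/β1 and PI3K/AKT signalling. With NAC, 18 of 19 measured collagen chains, 19 of 27 genes of collagen processing, 10 of 20 genes of the unfolded protein response and 14 of 37 cell cycle genes were higher. Camera called each of these lists, but not with an estimated correlation (adjusted p = 0.0920 for both collagen lists and the unfolded protein response, and adjusted p = 0.124 for the cell cycle). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, was lower. Col1a1, the main collagen of tendon, went from 2731 ± 124 to 5453 ± 253 FPKM (SD, n = 3), and Fn1, which encodes fibronectin, from 1719.9 ± 73.1 to 3276 ± 36.6 FPKM. Of 12733 genes tested with limma on log2(FPKM + 1), 774 were higher and 346 lower with NAC at a Benjamini-Hochberg adjusted p under 0.05. Their 3 NAC values all lay on one side of the 3 Control values in each of these 1120 genes. Such separation was seen in 32.6% of all tested genes, against 10% by chance. An unadjusted p under 0.05 was reached by 3355 genes, and an absolute log2 fold change of at least 1 by 34 of the higher and 9 of the lower genes. Leaving out 1 library lowered the counts in most cases: 379 genes were higher and 83 lower without Control 1, 362 and 87 without Control 3, 294 and 56 without NAC 1, 264 and 51 without NAC 2, and 456 and 141 without NAC 3, against 859 and 347 without Control 2. Values in parentheses after a library left out are the log2 fold changes without it. The authors' scaling holds the median log2 fold change of all tested genes near 0 (-0.0063). Scaled to library totals that median was -0.16 and the split became 467 higher and 3722 lower (11.1% higher), and with quantile normalization it was 567 and 408 (58.2% higher), against 69.1% as deposited.

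**Figure D1:**
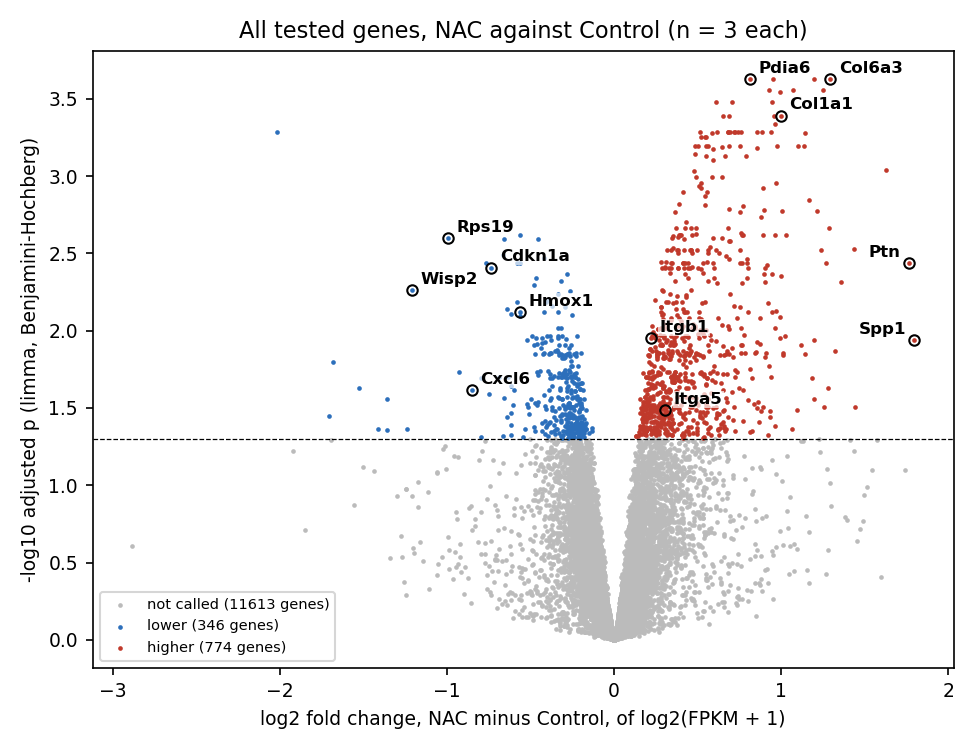
Each point is 1 of the 12733 tested genes, with the log2 fold change of NAC against Control (n = 3 each) on the x axis and -log10 of the limma adjusted p on the y axis. Above the dashed line, an adjusted p of 0.05, lie 774 genes higher with NAC (red) and 346 lower (blue), and ringed points carry their gene symbol.

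Collagens rose almost as a class. Of 19 measured collagen chains 18 rose and none fell, and 19 rose and none fell adjusted over the list alone, with Col8a1 the chain short of the threshold over all genes (adjusted p = 0.127; chosen after its value was seen). Col6a3 rose by 1.30 ± 0.0482 (log2, SE, limma adjusted p = 2.34e-04), from 17.9 ± 0.810 to 45.4 ± 1.34 FPKM. The basement membrane chains Col4a1 and Col4a2 went from 294 ± 12.6 to 575 ± 32.4 FPKM and from 303 ± 14.0 to 589 ± 27.0 FPKM (SD, n = 3). The list's median log2 fold change was 0.75 (camera adjusted p = 2.30e-21; adjusted p = 0.0920 with an estimated correlation). Of 27 genes of collagen processing and crosslinking 19 rose and none fell (25 and 0 adjusted over the list alone). They included Loxl1, a lysyl oxidase that crosslinks collagen and elastin (172 ± 7.53 to 269.6 ± 7.72 FPKM), the prolyl hydroxylase P3h1 (46.6 ± 0.903 to 61.8 ± 1.56 FPKM) and the collagen chaperone Fkbp10 (137 ± 1.67 to 171 ± 2.57 FPKM). The median of that list was 0.32 (camera adjusted p = 1.37e-17; adjusted p = 0.0920 with an estimated correlation). Sparc, a collagen-binding glycoprotein of the same list, rose from 2984 ± 52.5 to 4117 ± 146 FPKM, a call lost under quantile normalization (0.030). That normalization gives genes of the same rank the same value in every library. A gene as abundant as Sparc in all libraries can hardly rise under it, so this loss says little about Sparc.

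Among matrix proteases and their inhibitors 6 of 18 rose and none fell (8 and 1 adjusted over the list alone). Plau, the urokinase plasminogen activator, rose from 13.7 ± 1.46 to 31.3 ± 1.39 FPKM (SD, n = 3; limma adjusted p = 6.36e-04). Mmp2, a gelatinase, was called at a log2 fold change of 0.21, which turned to -0.038 under quantile normalization, and its call was lost without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.19 to 0.22) and with library totals (0.036). The median of the list was 0.12 (camera adjusted p = 0.00621; adjusted p = 0.117 with an estimated correlation) but turned to -0.052 with library totals and to -0.025 with quantile normalization, where the call ended (adjusted p = 0.369, range over all settings 0.00122 to 0.369). In the hyaluronan and proteoglycan list 5 of 21 rose and 1 fell (5 and 2 adjusted over the list alone). Gpc3, a cell-surface heparan sulfate proteoglycan, went from 19.2 ± 1.39 to 47.1 ± 0.581 FPKM and Cemip, a hyaluronan-binding protein, from 201 ± 17.8 to 371 ± 23.6 FPKM. The gene listed as AABR07073181.1, matched to Hspg2 (perlecan) through an older name, went from 117 ± 5.53 to 254 ± 24.1 FPKM. Gpc4 and Sdc1 also rose and Chpf fell, the last pair chosen after their values were seen. The median, 0.076, became -0.079 with library totals, and camera did not call the list (adjusted p = 0.159), whereas fry, which tests whether members move one way without comparison to other genes, did (adjusted p = 0.00215). Mmp2 also lost its call without a filter, without a trend and with the replicate block.

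Of the genes in the title, those of the integrin rose slightly and those of the kinases did not pass the test. These are RNA levels, which do not measure the activity of the kinases, so they leave open whether PI3K/AKT signalling changed. Itga5 (ENSRNOG00000057451; chromosome 7, 144970444 to 144993652), the integrin α5 subunit, went from 54.2 ± 4.57 to 67.2 ± 1.98 FPKM (SD, n = 3), a log2 fold change of 0.31 ± 0.0635 (SE, limma adjusted p = 0.0328). Itgb1 (ENSRNOG00000010966; chromosome 19, 61677542 to 61725535), its β1 partner, went from 296 ± 5.36 to 345 ± 4.11 FPKM (0.22 ± 0.0321, adjusted p = 0.0112). Pik3ca (ENSRNOG00000056371; chromosome 2, 118831350 to 118861454), the catalytic subunit of PI3K, stood at 10.2 ± 0.405 and 10.2 ± 0.566 FPKM in Control and NAC (adjusted p = 0.978). Akt1 (ENSRNOG00000028629; chromosome 6, 137218376 to 137236258) stood at 90.0 ± 3.93 and 98.1 ± 0.119 FPKM (adjusted p = 0.113), and among the leave-outs passed without Control 2 (0.16, adjusted p = 0.0485, range over all settings 0.0485 to 0.381). Coordinates are those of the deposited table, whose genome build is not given in the sources used here. Among 13 integrin subunits 6 rose and none fell, the same count adjusted over the list alone. Itga3, a laminin receptor subunit, rose from 39.2 ± 1.92 to 67.1 ± 1.73 FPKM and Itgav from 69.3 ± 3.46 to 90.1 ± 1.66 FPKM, with Itga11 and Itga8 the remaining pair (Itga8 chosen after its value was seen). The integrin list had a median of 0.23 (camera adjusted p = 1.63e-04; adjusted p = 0.117 with an estimated correlation), 0.064 with library totals and 0.14 with quantile normalization. In the PI3K and AKT list none of 30 rose and 1 fell (0 and 0 adjusted over the list alone). The gene that fell was Irs2, an insulin receptor substrate, from 8.17 ± 0.473 to 6.35 ± 0.388 FPKM. That list's median was -0.0042 (camera adjusted p = 0.719), and it turned to 0.014 without Control 3 and 0.0075 without NAC 3. The Itga5 call ended without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.26 to 0.32) and with library totals (0.14). The Itgb1 call ended without NAC 1 or NAC 2 (0.22 to 0.23), with library totals (0.047) and with quantile normalization (0.036), whereas that of Irs2 ended when any 1 of the 6 libraries was left out (-0.36 to -0.27). Itga11 lost its call without Control 1, Control 3, NAC 1 or NAC 2 (0.20 to 0.25), with library totals (0.060) and with quantile normalization (0.11). These lists, like the tendon list, follow the title, which may have been chosen from these same libraries, so they are not independent evidence of direction. Itga5 also lost its call without a filter, without a trend and with the replicate block, and Itga11 without a filter and without a trend. Irs2 also lost its call without a filter and with the replicate block.

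**Figure D2:**
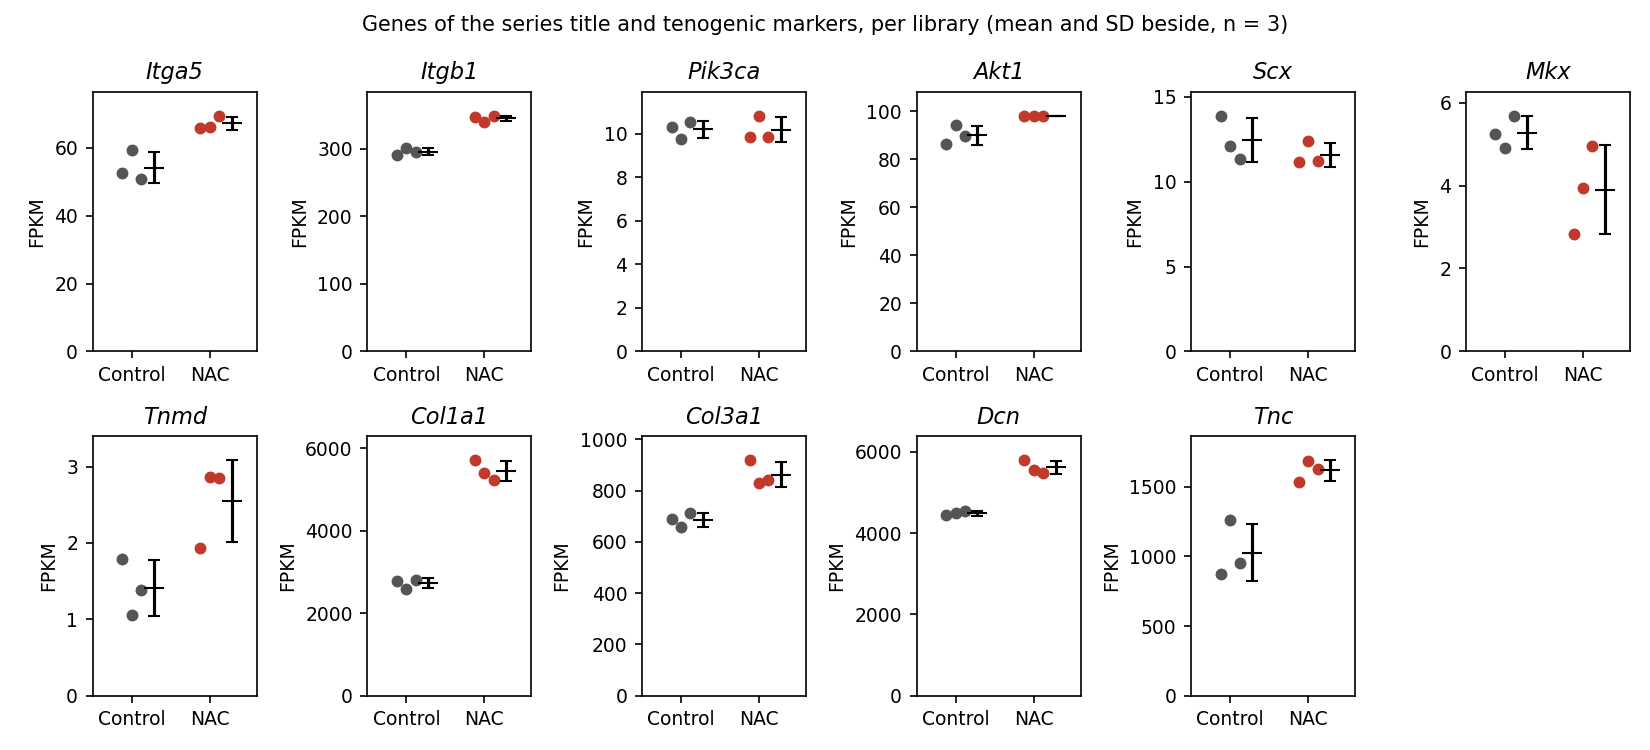
FPKM of the genes of the title and of tenogenic markers in each library, with Control in grey and NAC in red and the mean with its SD beside each group (n = 3) and each axis starting at 0. Itga5, Itgb1, Col1a1, Col3a1, Dcn and Tnc were higher with NAC, and Pik3ca, Akt1, Scx, Mkx and Tnmd did not pass the test as deposited.

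In the tendon list 4 matrix genes rose, and the transcription factors Scx and Mkx did not pass the test as deposited. Scx, which drives tendon development, stood at 12.5 ± 1.30 and 11.6 ± 0.7002 FPKM in Control and NAC (SD, n = 3; limma adjusted p = 0.519), and Mkx at 5.28 ± 0.394 and 3.90 ± 1.07 FPKM (adjusted p = 0.192). Mkx passed as lower with library totals (-0.52, adjusted p = 0.0481, range over all settings 0.0481 to 0.374). Tnmd, a marker of mature tenocytes, stood at 1.41 ± 0.369 and 2.55 ± 0.537 FPKM (adjusted p = 0.0909). Of 22 measured members 4 rose, none fell and 18 were not called (8 and 0 adjusted over the list alone). These were the small leucine-rich proteoglycans Lum (774 ± 22.2 to 1495 ± 38.1 FPKM), Bgn (1743 ± 5.79 to 2554 ± 60.3 FPKM) and Dcn (4489 ± 54.6 to 5620.4 ± 164 FPKM) and the glycoprotein Tnc (1028 ± 203 to 1618 ± 76.2 FPKM). Col3a1, in the collagen list, rose from 686 ± 27.6 to 863 ± 50.02 FPKM. In the tendon list 14 of the 22 log2 fold changes were above 0. They ran from -1.55, for a member that was not called, to 0.95, with a mean of 0.17. The tendon list's median was 0.27 (camera adjusted p = 0.00957; adjusted p = 0.117 with an estimated correlation), 0.10 with library totals and 0.12 with quantile normalization, where the call ended (adjusted p = 0.257, range over all settings 1.70e-04 to 0.257). The Bgn and Dcn calls also ended there (0.031 and 0.048), in a setting where genes this abundant in all libraries can hardly rise. The Tnc call ended without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.56 to 0.71), and the Col3a1 call without Control 1, NAC 1 or NAC 2 (0.28 to 0.36), with library totals (0.16) and with quantile normalization (0.15). Dcn also lost its call without a filter, and Tnc without a filter and without a trend.

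The bone list had 1 of 9 members higher and none lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.253, fry adjusted p = 0.0193). This was Spp1, osteopontin, which rose from 57.0 ± 24.6 to 191 ± 22.5 FPKM (SD, n = 3; limma adjusted p = 0.0115) and lost its call without NAC 2 (1.71). The cartilage list had 4 members measured, too few for the list test, and none passed either over all genes or adjusted over the list alone. Sox9, the chondrogenic transcription factor, stood at 9.60 ± 2.03 and 8.72 ± 0.751 FPKM (adjusted p = 0.643) and Matn4 at 10.6 ± 2.86 and 9.10 ± 0.198 FPKM (adjusted p = 0.586), although Matn4 passed without Control 2 (-0.39) and the Sox9 value turned to 0.040 there. The fat list had 3 of 11 higher and none lower (5 and 0 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.00678; adjusted p = 0.117 with an estimated correlation). Dgat2, a triglyceride synthesis enzyme, rose from 12.9 ± 0.0401 to 22.1 ± 0.776 FPKM. The transcription factor Cebpa (0.46) and the complement protease Cfd (1.098) rose too. The Cebpa call was lost without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.42 to 0.51) and with library totals (0.30). The Cfd call was lost without Control 3, NAC 1, NAC 2 or NAC 3 (1.01 to 1.20). That list was not called at a mean FPKM of at least 5 (adjusted p = 0.0733) or with quantile normalization (adjusted p = 0.0715, range over all settings 2.25e-04 to 0.117). In the stem and progenitor surface list 2 of 11 rose and none fell, the same adjusted over the list alone (camera adjusted p = 0.0940). Cd9 and Alcam went from 347 ± 19.7 to 406 ± 4.02 FPKM and from 36.4 ± 2.67 to 46.1 ± 2.21 FPKM. Both calls were lost with library totals (0.053 and 0.16). That of Cd9 was also lost without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.20 to 0.23) and with quantile normalization (0.027), and that of Alcam without Control 1, Control 3, NAC 1 or NAC 2 (0.27 to 0.35). That median of 0.14 turned to -0.035 with library totals and -0.016 with quantile normalization, and the list was called without Control 2 (median 0.12, adjusted p = 0.0242, range over all settings 0.0242 to 0.674). Cebpa and Cd9 also lost their calls without a filter, without a trend and with the replicate block, and Cfd without a filter. Alcam also lost its call without a filter and without a trend.

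In the unfolded protein response list 10 of 20 rose and none fell (10 and 1 adjusted over the list alone), among them chaperones and disulfide isomerases, which fold secreted proteins. Pdia6 went from 247 ± 4.37 to 434 ± 6.39 FPKM (SD, n = 3; limma adjusted p = 2.34e-04), Pdia4 from 128 ± 3.86 to 206 ± 6.66 FPKM, Hsp90b1 from 286 ± 7.55 to 400.1 ± 8.10 FPKM and Hspa5 (BiP) from 325 ± 3.00 to 419 ± 7.13 FPKM. The median of the list was 0.18 (camera adjusted p = 4.98e-06; adjusted p = 0.0920 with an estimated correlation), 0.011 with library totals. In the amino acid response list 7 of 28 rose and 1 fell (7 and 4 adjusted over the list alone). The proline and serine synthesis enzymes Pycr1 (10.96 ± 1.86 to 20.6 ± 2.33 FPKM) and Psat1 (2.38 ± 0.234 to 4.42 ± 0.351 FPKM) and the transporters Slc1a5 (14.6 ± 0.780 to 20.5 ± 0.761 FPKM) and Slc38a2 (171 ± 1.17 to 208 ± 0.868 FPKM) rose, and Atf5 fell (-0.30; chosen after its value was seen). Pycr1 lost its call without NAC 1 or NAC 2 (0.80 to 0.81). That list missed the threshold (median 0.13, -0.025 with library totals; camera adjusted p = 0.0790) and passed with library totals (adjusted p = 0.0326) and without Control 2 (median 0.20, adjusted p = 0.0132, range over all settings 0.0132 to 0.490). In the cholesterol synthesis list 6 of 23 rose and none fell, the same adjusted over the list alone. Insig1, a sterol-regulated protein of the endoplasmic reticulum, rose from 16.0 ± 1.18 to 21.9 ± 1.17 FPKM, a call lost without NAC 1 or NAC 2 (0.40 to 0.43). The median was 0.19 (camera adjusted p = 1.48e-04; adjusted p = 0.148 with an estimated correlation).

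Of the measured cell cycle genes 14 rose, and of the p53 target and arrest genes 7 fell. Ccnd1, cyclin D1, went from 81.6 ± 7.68 to 130.5 ± 5.14 FPKM (SD, n = 3; limma adjusted p = 0.00330), the mitotic kinase Cdk1 from 12.2 ± 1.54 to 21.995 ± 0.785 FPKM, Rrm2 from 13.1 ± 0.969 to 21.9 ± 1.16 FPKM and Top2a from 3.40 ± 0.458 to 6.67 ± 0.634 FPKM. The cell cycle list had 37 measured members, of which 14 rose and none fell (26 and 0 adjusted over the list alone), and the log2 fold change was above 0 in all 37. Their median was 0.44 (camera adjusted p = 1.38e-12; adjusted p = 0.124 with an estimated correlation), 0.33 with library totals. Among cell cycle arrest genes and p53 targets none of 20 rose and 7 fell (3 and 7 adjusted over the list alone). Cdkn1a fell from 122 ± 6.93 to 73.3 ± 7.93 FPKM (adjusted p = 0.00391), cyclin G1 (Ccng1) from 66.9 ± 3.60 to 47.7 ± 2.43 FPKM, Mdm2, the ubiquitin ligase of p53, from 37.4 ± 1.22 to 26.8 ± 2.40 FPKM and Zmat3 from 31.2 ± 2.35 to 23.2 ± 0.549 FPKM. Mdm2 lost its call without NAC 1 (-0.44) and Zmat3 without NAC 2 (-0.39). The list as a whole missed the threshold (median -0.098, camera adjusted p = 0.0624), also with an estimated correlation (adjusted p = 0.267), and its adjusted p ran from 0.0166 to 0.267 over all settings. It passed without Control 1 (adjusted p = 0.0394) or NAC 3 (adjusted p = 0.0256), at a mean FPKM of at least 5 (adjusted p = 0.0166) and without a filter (adjusted p = 0.0282). It also passed with limma voom (adjusted p = 0.0406) and with fry (adjusted p = 0.0214).

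**Figure D3:**
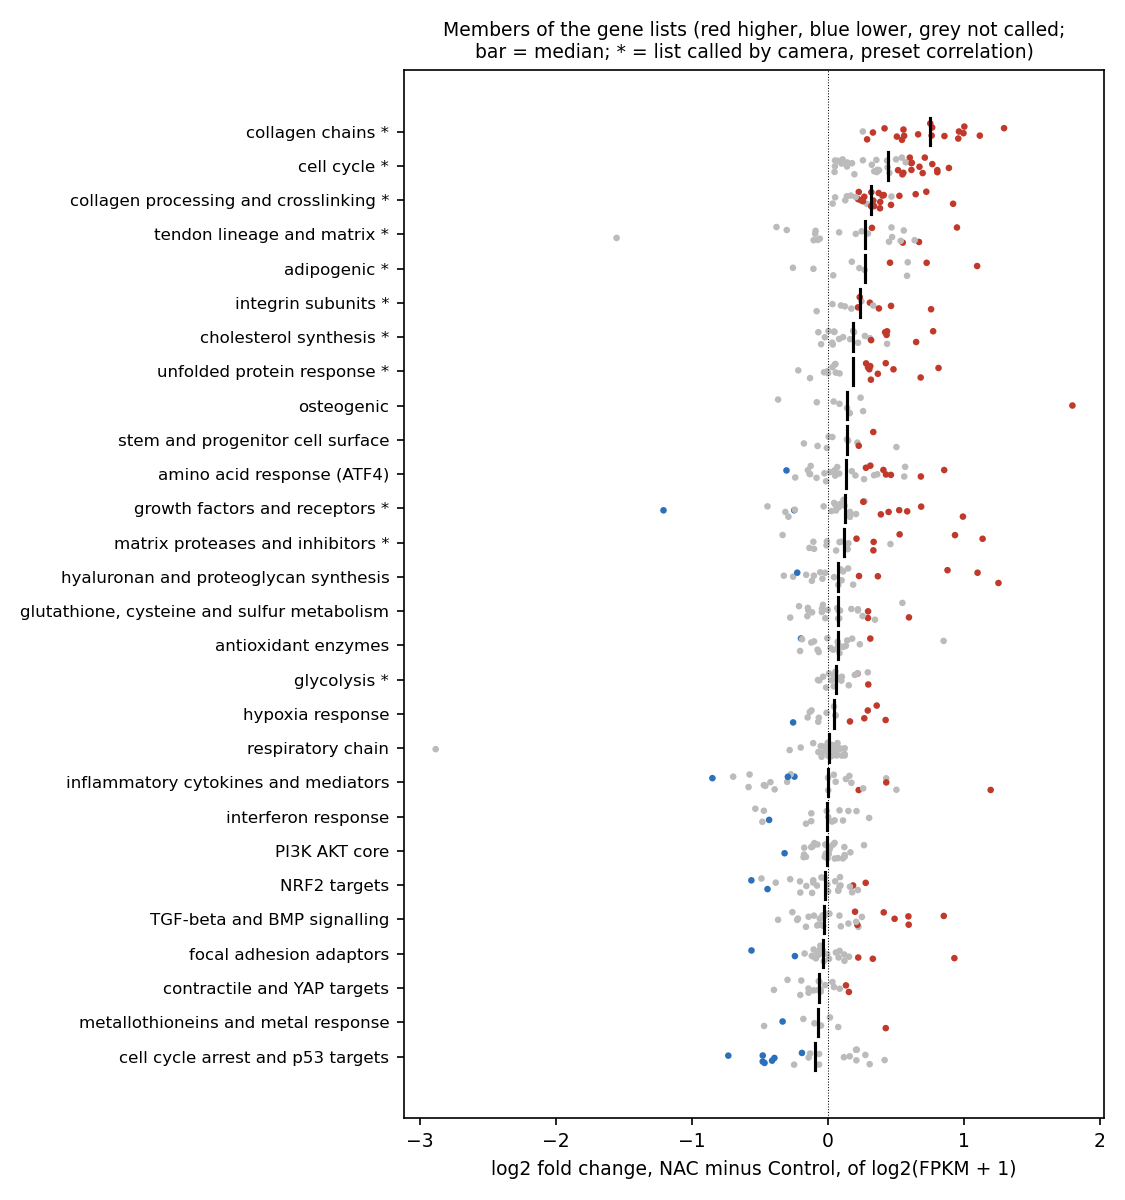
Log2 fold changes of the measured members (points) of each fixed gene list with at least 5 of them, with red for genes higher with NAC, blue for lower and grey for not called, a bar at the list's median, and an asterisk for the 11 lists that camera called with its preset correlation. Medians run from -0.10 for cell cycle arrest and p53 targets to 0.75 for the collagen chains as deposited, and among the called lists those of matrix proteases, growth factors and glycolysis turn below 0 with library totals.

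Genes of redox and thiol metabolism, where NAC acts as an antioxidant and cysteine source, were not called as groups by camera, while fry called 1 of the 4 lists, that of glutathione, cysteine and sulfur metabolism (adjusted p = 0.0479). Of 27 NRF2 targets 2 rose and 2 fell (3 and 3 adjusted over the list alone). Hmox1, heme oxygenase 1, fell from 96.8 ± 8.59 to 65.1 ± 3.85 FPKM (SD, n = 3; limma adjusted p = 0.00757) and Ephx1 from 8.46 ± 0.690 to 5.95 ± 0.324 FPKM. Tkt (0.18) and Gsta4 (0.28) rose. The Ephx1 call was lost without Control 1, NAC 1 or NAC 2 (-0.44 to -0.39). The Tkt call was lost without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.17 to 0.19) and the Gsta4 call when any 1 of the 6 libraries was left out (0.24 to 0.32). With library totals both Tkt (0.012) and Gsta4 (0.11) lost theirs, and Tkt also with quantile normalization (0.11). The list's median was -0.023 (camera adjusted p = 0.671) and turned to 0.0082 without Control 2. In the glutathione, cysteine and sulfur list 3 of 25 rose and none fell (6 and 3 adjusted over the list alone). They were the peptidase Anpep (125 ± 17.3 to 189 ± 10.2 FPKM), Ggt7 (13.7 ± 0.254 to 17.1 ± 0.752 FPKM) and Acy1, an aminoacylase that deacetylates N-acetylated amino acids (13.0 ± 0.762 to 16.2 ± 0.216 FPKM). The Anpep call was lost without Control 3, NAC 1 or NAC 2 (0.56 to 0.62). The Ggt7 call was lost without Control 1, Control 3, NAC 1 or NAC 2 (0.26 to 0.32) and the Acy1 call without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.25 to 0.30), the last pair also with library totals (0.13 and 0.13). That median, 0.075, turned to -0.081 with library totals and -0.0013 without Control 1 (camera adjusted p = 0.330). Of 23 antioxidant enzymes 1 rose and 1 fell, the same adjusted over the list alone. Prdx4, the peroxiredoxin of the endoplasmic reticulum, rose from 84.1 ± 1.26 to 105 ± 4.79 FPKM, a call lost with library totals (0.14). Sod2, the mitochondrial superoxide dismutase, fell from 897 ± 9.05 to 782 ± 5.06 FPKM, a call lost without Control 1, Control 3, NAC 1 or NAC 2 (-0.20 to -0.19). The list's median of 0.072 (camera adjusted p = 0.264) turned to -0.10 with library totals and -0.037 with quantile normalization. Of 8 metal response genes 1 rose and 1 fell (1 and 3 adjusted over the list alone; median -0.075, camera adjusted p = 0.360). The zinc transporter Slc39a14 fell by 0.33 and Slc39a10 rose by 0.43, calls that were lost without NAC 1 or NAC 2 (-0.33 to -0.32) and without Control 3, NAC 1 or NAC 2 (0.37 to 0.44). Ephx1, Ggt7 and Acy1 also lost their calls with the replicate block, and Tkt without a trend and with the replicate block. Gsta4 also lost its call without a filter, without a trend and with the replicate block, and Sod2 without a filter and without a trend.

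Growth factor genes moved both ways. Igfbp7, an insulin-like growth factor binding protein, rose from 323 ± 6.12 to 644 ± 34.5 FPKM (SD, n = 3; limma adjusted p = 2.83e-04) and Hgf, hepatocyte growth factor, from 25.1 ± 1.28 to 41.0 ± 2.27 FPKM. Wisp2, a matricellular CCN protein, fell from 28.1 ± 5.96 to 11.4 ± 0.245 FPKM and Fgf7 from 422 ± 8.10 to 355 ± 4.58 FPKM, the latter call being lost without NAC 2 (-0.25). In this list 7 of 29 rose and 2 fell (10 and 5 adjusted over the list alone). Its median, 0.12 (camera adjusted p = 0.0138; adjusted p = 0.117 with an estimated correlation), turned to -0.049 with library totals, and the call ended with quantile normalization (adjusted p = 0.0797, range over all settings 0.00202 to 0.117). Of 31 TGF-beta and BMP genes 7 rose and none fell (8 and 2 adjusted over the list alone). The latent TGF-beta binding proteins Ltbp2 (488 ± 18.7 to 736 ± 17.1 FPKM) and Ltbp3 (97.6 ± 1.85 to 138 ± 4.13 FPKM), Fst, follistatin (84.8 ± 1.56 to 129 ± 11.5 FPKM), and Id1 (36.3 ± 1.63 to 48.6 ± 3.20 FPKM) were among them. The list's median, -0.027, and its mean, 0.079, differed in sign, the test pointed upward (camera adjusted p = 0.302, fry adjusted p = 0.0138), and without Control 2 the median was 0.020. Of 24 focal adhesion genes 3 rose and 2 fell (4 and 2 adjusted over the list alone). Fn1 rose, as did Vcl (0.22) and Tln2 (0.33), and Lims2 (16.0 ± 1.01 to 10.5 ± 0.871 FPKM) and Parva (chosen after its value was seen) fell. Vcl lost its call without Control 1, Control 3, NAC 1 or NAC 2 (0.20 to 0.22) and Tln2 when any 1 of the 6 libraries was left out (0.29 to 0.38). Both lost it with library totals (0.050 and 0.18), Vcl also with quantile normalization (0.15). The median was -0.034, the mean 0.016 and the direction of the test downward (camera adjusted p = 0.914). Of 18 contractile and YAP target genes 2 rose and none fell (2 and 1 adjusted over the list alone; median -0.065, camera adjusted p = 0.189). These were Axl (0.15, -0.019 with library totals and, not called, 0.068 with quantile normalization) and Tagln2 (0.13, -0.042 with library totals and -0.066 with quantile normalization). The Axl call was lost without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.15 to 0.16). The Tagln2 call was lost when any 1 of the 6 libraries was left out (0.12 to 0.14). That list was called lower with quantile normalization (median -0.15, adjusted p = 9.29e-04) and without Control 3 (median -0.11, adjusted p = 0.0442, range over all settings 9.29e-04 to 0.678). Vcl and Axl also lost their calls without a trend and with the replicate block, and Tln2 without a filter and with the replicate block. Tagln2 also lost its call without a filter, with median-of-ratios rescaling, without a trend, with the replicate block and at a mean of at least 10 recovered reads.

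Inflammatory genes moved in opposite directions. C3, the central complement component, rose from 714 ± 25.8 to 1639 ± 76.2 FPKM (SD, n = 3; limma adjusted p = 2.34e-04) and the NF-kappaB inhibitor Tnfaip3 from 23.9 ± 0.564 to 32.5 ± 1.90 FPKM. Icam1, an adhesion molecule, fell from 77.2 ± 2.20 to 62.7 ± 1.05 FPKM, and the neutrophil chemokine Cxcl6 from 257 ± 39.4 to 143 ± 28.7 FPKM. Of 25 measured mediators 3 rose and 3 fell (3 and 4 adjusted over the list alone), the others being Csf1, which rose by 0.23, and Ccl7, which fell (chosen after its value was seen). The Cxcl6 call was lost without Control 1, Control 3, NAC 1 or NAC 2 (-0.86 to -0.74), and that of Csf1 without Control 1, Control 3, NAC 1 or NAC 2 (0.20 to 0.23), with library totals (0.052) and with quantile normalization (0.074). The median of 0.00081 turned to -0.17 with library totals and -0.20 with quantile normalization. It was -0.26 without Control 1, -0.021 without Control 2, -0.15 without Control 3, -0.023 without NAC 2 and -0.12 without NAC 3. Its mean (-0.078) and its test pointed downward (camera adjusted p = 0.719). Among 16 interferon response genes none rose and 1, Gbp2, fell (1 and 2 adjusted over the list alone), from 9.25 ± 0.445 to 6.60 ± 0.359 FPKM, a call lost without NAC 2 (-0.40). The interferon list had a median of -0.0033 (camera adjusted p = 0.512, fry adjusted p = 0.0214). Cxcl6 also lost its call without a filter.

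Of 20 glycolysis genes 2 rose and none fell (3 and 0 adjusted over the list alone), namely Pfkfb3 (29.7 ± 1.36 to 36.7 ± 1.07 FPKM) and Pfkm (23.1 ± 0.813 to 27.0 ± 0.692 FPKM). The Pfkfb3 call was lost without Control 1, NAC 1 or NAC 2 (0.27 to 0.30) and the Pfkm call without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.20 to 0.24). Both were lost with library totals (0.13 and 0.051). The list was called at a median of 0.057 (camera adjusted p = 0.0319; adjusted p = 0.490 with an estimated correlation), but this turned to -0.12 with library totals and -0.024 with quantile normalization. The call ended in several settings, which included leaving out Control 1 (adjusted p = 0.136), Control 3 (adjusted p = 0.0690) or NAC 3 (adjusted p = 0.133, range over all settings 0.00400 to 0.996), and fry (adjusted p = 0.148). Of 15 hypoxia response genes 5 rose and 1 fell, the same adjusted over the list alone. Egln3 (73.8 ± 6.60 to 99.3 ± 5.62 FPKM), Car9 (48.8 ± 2.50 to 62.8 ± 2.67 FPKM), the prolyl hydroxylase P4ha1 (154 ± 2.74 to 186 ± 8.02 FPKM), Adm and Ero1l rose and the demethylase Kdm3a fell (12.9 ± 0.642 to 10.6 ± 0.187 FPKM), Adm and Ero1l being chosen after their values were seen. Car9 lost its call without NAC 2 (0.32) and Egln3 without Control 1, Control 3, NAC 1 or NAC 3 (0.38 to 0.42). The P4ha1 call was lost without Control 1, NAC 1 or NAC 2 (0.23 to 0.27), and that of Kdm3a without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (-0.26 to -0.23). P4ha1 also lost it with library totals (0.094) and with quantile normalization (0.15). The median, 0.045 (camera adjusted p = 0.253), turned to -0.13 with library totals and -0.053 with quantile normalization. None of 36 nuclear genes of the respiratory chain passed, over all genes or adjusted over the list alone. Cox4i1 stood at 285 ± 8.40 and 295 ± 3.73 FPKM in Control and NAC (SD, n = 3; limma adjusted p = 0.441) and Cox6a1 at 338 ± 13.6 and 338 ± 13.8 FPKM (adjusted p = 0.97503). With library totals both passed as lower (-0.13 and -0.17). The list's median was 0.011, its mean -0.071 and its test upward (camera adjusted p = 0.719). The median turned to -0.16 with library totals, where the list was called lower (adjusted p = 0.0375, range over all settings 0.0375 to 0.886), -0.047 with quantile normalization, -0.011 without Control 3 and -0.012 without NAC 3. Pfkfb3 and Egln3 also lost their calls with the replicate block, and Pfkm without a trend and with the replicate block. Kdm3a also lost its call without a filter, without a trend and with the replicate block.

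Outside the lists, Ptn, pleiotrophin, a heparin-binding growth factor, rose from 48.0 ± 11.4 to 164 ± 25.4 FPKM (SD, n = 3; limma adjusted p = 0.00365). Tslp, an epithelial-type cytokine, rose from 46.1 ± 8.36 to 119.7 ± 19.8 FPKM and Cpz, a carboxypeptidase that binds Wnt proteins, from 9.32 ± 1.91 to 26.8 ± 3.23 FPKM. Cdhr4, a cadherin-related gene, rose from 11.6 ± 0.674 to 38.3 ± 6.39 FPKM, and the sodium pump subunit Atp1b1 from 6.09 ± 1.18 to 15.6 ± 1.24 FPKM. Slc25a48, a mitochondrial carrier, rose from 0.249 ± 0.312 to 2.08 ± 0.228 FPKM, with a call lost without Control 3, NAC 1 or NAC 2 (1.28 to 1.30). Rps19, a ribosomal protein gene, fell from 175 ± 3.18 to 87.8 ± 12.4 FPKM (adjusted p = 0.00252), a value that is uncertain, since ribosomal protein genes have near-identical copies. Dusp11 fell from 5.34 ± 2.24 to 1.42 ± 0.539 FPKM and Sytl2 from 8.997 ± 1.05 to 2.34 ± 1.499 FPKM. The Dusp11 call was lost without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (-1.53 to -1.22) and the Sytl2 call without Control 1, Control 2, Control 3, NAC 1 or NAC 2 (-1.98 to -1.62). The others among the 10 highest and 10 lowest named genes outside the lists were short RNAs with few reads: ACA64 had 3, 5 and 7 reads in Control and 0, 1 and 0 in NAC, and SNORA63 5, 3 and 5 against 2, 1 and 2. Mir345 had 4, 2 and 4 against 1, 1 and 0, Mir125a 1, 3 and 3 against 0, 0 and 0, and U7 2, 2 and 2 against 1, 0 and 0. Mirlet7d had 4, 4 and 8 reads in Control and 11, 14 and 17 in NAC, and each of these 6 calls was lost in at least 3 of the 6 fits that left out 1 library. Dusp11 also lost its call without a filter and with the replicate block, and Sytl2 with a pseudocount of 0.1, without a filter, without a trend and with robust estimation. SNORA63 also lost its call with a pseudocount of 0.1, without a filter, without a trend and with limma voom, and Mir345 and U7 with a pseudocount of 0.1, without a filter, without a trend, with the replicate block and with limma voom. Mir125a also lost its call with the replicate block and with limma voom, and Mirlet7d without a filter and with limma voom.

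Most markers of other cell types did not reach a mean FPKM of 1. None of 12 lymphocyte and mast cell markers or 9 red cell markers reached a mean FPKM of 1. Of 18 macrophage and leukocyte markers 4 were measured and none passed, with Cd14 at 14.0 ± 0.3998 and 15.3 ± 1.68 FPKM in Control and NAC (SD, n = 3; limma adjusted p = 0.426) and Lyz2 at 5.59 ± 0.972 and 5.27 ± 1.097 FPKM (adjusted p = 0.796). Of 14 endothelial markers 2 were measured and Flt1, a VEGF receptor gene, rose from 1.57 ± 0.254 to 2.75 ± 0.137 FPKM (adjusted p = 0.0309). Of 11 epithelial markers 3 were measured and Cldn3, a tight junction gene, rose from 0.773 ± 0.315 to 2.00 ± 0.200 FPKM (adjusted p = 0.0386), while the list's median was -0.016 and its mean 0.20. Flt1 lost its call without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.50 to 0.56) and Cldn3 without Control 1, Control 3, NAC 1, NAC 2 or NAC 3 (0.62 to 0.83) and with quantile normalization (0.80). Of 10 pericyte and smooth muscle markers 5 were measured, none rose and Myh11, smooth muscle myosin, fell from 21.9 ± 0.486 to 17.2 ± 1.40 FPKM (adjusted p = 0.0269), a call lost without Control 1, Control 2, Control 3, NAC 1 or NAC 2 (-0.35 to -0.27). That list, with enough members for the test, was not called (median -0.074, camera adjusted p = 0.683). Of 13 skeletal muscle markers 2 were measured, Tnnt3 at 24.3 ± 1.68 and 25.9 ± 0.847 FPKM (adjusted p = 0.363) and Acta1 at 4.20 ± 0.518 and 4.36 ± 0.744 FPKM (adjusted p = 0.880), and of 9 Schwann cell and nerve markers 1, S100b, at 50.01 ± 4.06 and 49.0 ± 3.09 FPKM (adjusted p = 0.852). Adjusted over each list alone the calls in these marker lists were the same. Flt1 also lost its call without a filter and with the replicate block, and Cldn3 with a pseudocount of 0.1, without a filter and with the replicate block. Myh11 also lost its call with the replicate block.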

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

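Library totals, limma voom on recovered reads, the minimum of 10 recovered reads and protein-coding genes only were chosen after the results were seen, and the other settings had been fixed in advance. The planned count tests with edgeR and DESeq2 on recovered reads were not run, and limma voom was run on those reads instead. The counts of 774 higher and 346 lower genes stayed within 1.5 times under a pseudocount of 0.1, a mean FPKM of at least 5, median-of-ratios rescaling, quantile normalization, robust estimation, the minimum of 10 recovered reads and protein-coding genes only. Without a filter 207 were lower, without a trend 206, and with voom 529. A stricter threshold left by construction 34 higher and 9 lower at an absolute log2 fold change of 1 and 238 and 32 at an adjusted p under 0.01. With library totals 467 were higher and 3722 lower, the median of all genes being -0.16. Leaving out 1 library gave 264 to 859 higher and 51 to 347 lower, fewest without NAC 2 and most without Control 2, and 11 to 13 lists. The 11 lists became 7 with quantile normalization and 0 with an estimated correlation, while fry called 16, without glycolysis and with 6 lists that camera did not call. The tendon list's median of 0.27 was no longer called with an estimated correlation (adjusted p = 0.117) and fell short at 0.12 with quantile normalization (adjusted p = 0.257), and the integrin list's 0.23 was not called with an estimated correlation (adjusted p = 0.117). Over single-library leave-outs the PI3K and AKT median ran from -0.020 to 0.014.

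With the replicate block 466 genes were higher and 110 lower. The deviations of same-numbered libraries correlated at 0.063, 0.059 and -0.050, and not every library correlated best with its own number (Control 3 and NAC 1, 0.065), so the numbers were not taken as a pairing.

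Of the 108 called named genes 64 kept their call in each setting fixed in advance that used all 6 libraries and tested them, the stricter thresholds aside. Some of these, such as Slc25a48 and Psat1, were not tested at a mean FPKM of at least 5. Of the 108 genes 54 lost their call in at least 1 leave-out, and 3 reversed. Log2 fold changes reversed with quantile normalization for Pik3ca (0.012), Tagln2 (-0.066), Mmp2 (-0.038), Cox6a1 (-0.18) and Cox4i1 (-0.11). With library totals they reversed for Akt1 (-0.049), Axl (-0.019), Tagln2 (-0.042), Cd14 (-0.054), Cox6a1 (-0.17), Cox4i1 (-0.13), Tnnt3 (-0.074) and Acta1 (-0.10). Leave-outs gave ranges across 0 for Pik3ca (-0.045 to 0.019), Sox9 (-0.20 to 0.040), Lyz2 (-0.22 to 0.042), Cox6a1 (-0.029 to 0.036), S100b (-0.083 to 0.032) and Acta1 (-0.063 to 0.14). Apart from the stricter thresholds and the smaller samples, the cause was not tested. Depth limits the short RNAs, whose calls rest on under 10 reads per library on average.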

Other observations

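The gene groups below and the tests of library scaling, transcript length, nuclear respiratory genes, gene copies and counting error were chosen after the results were seen, and the solute carrier test and the splits of the samples before. The bootstrap intervals of medians below resample the genes of a group as if independent, and not the libraries. They thus leave out the spread between libraries.

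Several genes of the basement membrane, complement and the lysosome rose with NAC. Camera tests of these groups are not given, since groups picked after the results were seen cannot be tested like the fixed lists. Of 8 measured laminin chains 7 rose and none fell, and both nidogens, which link laminin to collagen IV, rose. Lama5 went from 10.8 ± 1.36 to 25.5 ± 2.12 FPKM (SD, n = 3; limma adjusted p = 0.00143), Lamb2 from 142 ± 1.78 to 234 ± 11.8 FPKM and Nid1 from 228 ± 5.66 to 350.4 ± 9.56 FPKM. The laminin median was 0.56, and 0.42 with library totals. Of 13 complement components and regulators 9 rose and none fell, among them the proteases C1r (643 ± 41.3 to 1085 ± 67.6 FPKM) and C1s (645 ± 47.4 to 1091 ± 69.2 FPKM). Their median was 0.63, and 0.53 with library totals. Cathepsins rose in 6 of 9 cases and fell in none, such as the collagenolytic Ctsk from 59.7 ± 0.251 to 85.8 ± 0.685 FPKM (median 0.33, 0.15 with library totals). Of 27 lysosomal hydrolases 12 rose and none fell (median 0.27), but 9 rose and 6 fell with library totals.

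Of 79 cytosolic ribosomal protein genes 30 rose and 1 fell, with a median of 0.17 that turned to -0.00052 with library totals and -0.0062 with quantile normalization. With library totals 2 of them rose and 3 fell. None of 37 proteasome subunit genes was called (median 0.013, -0.033 with quantile normalization). With library totals 20 of these 37 were lower, at a median of -0.16, close to the shift of all genes (-0.16).

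In the joint rise of matrix and secretory genes, that of the collagen chains did not rest wholly on the authors' scaling, which differed between the groups. Their median was 0.58 with library totals (bootstrap 95% interval 0.37 to 0.78). This lay above a limit of 0.1, but that limit replaced one of 0.5 after the value was seen, which the interval did not clear. A change of scaling multiplies all values of a library by 1 factor, so what remains follows from the deposited median and tests no cause. For the other parts, whether they rose in themselves depended on the scaling. Their medians with library totals were 0.15 for collagen processing (interval 0.069 to 0.21), 0.011 for the unfolded protein response (interval -0.13 to 0.14) and -0.052 for matrix proteases and inhibitors (interval -0.15 to 0.16). All lay above the median of all genes there (-0.16), since 1 factor per library leaves the place of a list among the other genes nearly unchanged. Longer transcripts were not favoured, since the longest 1143 of the tested protein-coding genes had a median of -0.026, while better recovery of membrane-bound RNA would also raise the 155 measured solute carrier genes (10 higher, 6 lower and a median of 0.039 as deposited, interval -0.019 to 0.081, and 7, 45 and -0.13 with library totals), whose median lay far below that of the collagen processing genes (0.32). A response of the cells to NAC may account for the rise and remains a hypothesis, as do differences between the cultures that the labels do not record.

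Mitochondrially encoded protein genes rose in 10 of 13 cases and fell in none, with a median of 0.49 and 0.18 with quantile normalization. Mt-co2 went from 1585 ± 34.5 to 2552 ± 45.6 FPKM (SD, n = 3; limma adjusted p = 4.06e-04). With library totals the median was 0.31 (bootstrap 95% interval 0.21 to 0.34), so the rise did not rest wholly on the authors' scaling. This lay above a limit of 0.1, but that limit was set after the value was seen and replaced one of 0.4, which the value did not reach. As for the collagen chains, what remains follows from the deposited median and tests no cause. A joint rise with the nuclear respiratory genes was not seen, their median being 0.011 (interval -0.0034 to 0.048). A change in mitochondrial RNA with NAC may underlie this and was not tested further.

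In 26 genes with a mean of over 100 recovered reads the libraries of 1 group differed by over 4-fold. Ndufa1 (chosen after its values were seen), for example, had 146, 1.84 and 99.8 FPKM in Control and 4.84, 3.11 and 3.35 in NAC, and lowered the mean of the respiratory chain list. The reads of all 9590 tested genes of that depth were redrawn at random 100 times around each group's mean rate. Each draw gave 0 such genes, against the 26 observed. At this depth redrawn reads could hardly give another number, so no conclusion on counting error was drawn from them. Reads shared between near-identical copies may contribute, since copy-type names were over-represented (11 of 26 genes, odds ratio 6.31, 95% interval 2.62 to 14.8 by Fisher's exact test), while the other genes carry no such name and stay unexplained.

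The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split called 1120 genes and the highest other split 2, and 1 of the 10 splits, the real one, gave as many. It called 11 lists, and again 1 of 10 gave as many. The other splits, which mix the groups, called 2 to 8 lists although each called at most 2 genes.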
